A study of Rattus norvegicus with 4 samples.

How the data were processed

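RNA was sequenced from MMQ cells, a rat pituitary tumour cell line that secretes prolactin, grown with 2.5% fetal bovine serum and 15% horse serum. Cells received the dopamine D2 receptor ligand UNC9994 at 15 µM or its vehicle DMSO for 12 h or 24 h. Each of the 4 combinations of treatment and time was represented by 1 library, so no combination had a replicate. Per the labels' protocols, polyadenylated RNA was selected from DNase-treated total RNA and reverse-transcribed with random hexamers, and the cDNA was fragmented by nebulization. Strand handling, read length and sequencing batch are not given in the sources used here. A drug library and its vehicle library could therefore also differ by culture or batch, and the p-values below measure only the spread among these 4 libraries.

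The deposited values are FPKM (fragments per kilobase of gene model, scaled to library size), per the file headers, for gene IDs of the Ensembl form and for IDs without an Ensembl number. The name of the series table speaks of raw counts, which its header and its values contradict. Per the submitters' processing notes, CASAVA, TopHat2 version 2.0.7, Bowtie2, HTSeq and the rat build Rnor_6.0 were used. Their roles, the annotation release and the origin of the IDs without an Ensembl number are not given in the sources used here. The series table held 35042 rows. Of these, 1209 were exact repeats listed at 0 and were removed, as was 1 row with a truncated ID, also listed at 0. The remaining 33832 IDs comprised 32883 Ensembl IDs and 949 others, of which 20297 were above 0 in at least 1 library. The single-sample tables held the same value for every one of these 33832 IDs.

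The files do not pair the IDs with gene names. The gene table at hand lists 47357 rat genes with an Ensembl ID for 0 of them, so 0 IDs could be named. The 23 gene lists fixed before the data were examined (653 genes, covering lactotroph identity, dopamine signalling, stress responses, sterol synthesis, cell cycle, other cell types and others) and the genes chosen by name, among them prolactin and the D2 receptor, are therefore not analysed here. The 4 IDs printed are those with the 2 highest and the 2 lowest log2 fold changes among Ensembl IDs past the threshold, with a mean log2(FPKM + 0.5) of at least 1 and the same direction at both times. This is the naming rule fixed in advance, without its condition on gene symbols and shortened to 4 IDs.

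Read numbers were recovered from the deposited FPKM. The 4 divisors used by the authors were first estimated from 3897 IDs above 0 in every library and under 2 FPKM. Of these, 3258 (83.6%) stood in ratios of whole numbers, with a lowest read number of at most 30 and a tolerance of 0.0002, and the others were left out of this first step. Then, for every ID, the shortest gene model length of at least 40 bases was found that made all 4 read numbers whole within 0.001 reads plus 1e-08 of the value. All 16009 IDs above 0 in every library gave whole reads. When the values of 500 IDs were disturbed at random by up to 1%, 0 gave whole reads. A common factor of all 4 read numbers cannot be excluded for single IDs, and IDs above 0 in only 1 library are poorly determined. Recovered totals were 19933310 reads for DMSO at 12 h, 17433867 for DMSO at 24 h, 21728374 for UNC9994 at 12 h and 21188668 for UNC9994 at 24 h. They were 99.6%, 98.2%, 95.6% and 98.6% of the divisors, and median-of-ratios factors computed on the deposited FPKM lay between 0.999 and 1.002. The recovered reads were used for filters, for counting intervals (exact binomial, 95%, counting error only) and in 1 alternative fit.

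The tests had been planned on counts. The main test was instead run on the deposited FPKM, with limma (version 3.58.1, R 4.3.3) on log2(FPKM + 0.5). It had terms for time and treatment, an expression trend in the prior variance and Benjamini-Hochberg adjustment at 0.05. The planned fit to counts was not run, although the recovered reads would have allowed it. The pseudocount, the filter and the variance trend replaced settings planned for counts. They were chosen after the data were examined, when fits with pseudocounts of 0.1, 0.5 and 1, with robust moderation and with limma-voom had already been run on these libraries. The comparisons, the groups, the threshold and most alternatives were set before the data were examined. The test ran on the 14056 IDs with at least 10 recovered reads in at least 2 libraries. The fit has 1 residual degree of freedom, moderated across IDs with 4.48 prior degrees of freedom. Its error is the extent to which the treatment effect differed between the 2 times, so it tests a change common to both. Fold changes on the log2(FPKM + 0.5) scale understate the change of IDs of low abundance. The response at a single time and the difference of the response between times have no residual degree of freedom and carry no p-value. For pairs of libraries, IDs were counted when the log2 ratio reached 2-fold and the CPM of the recovered reads reached 5 in 1 of the libraries compared. The number expected from counting error alone came from 20 Poisson draws. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the other steps.

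The fit was tested on simulated data for this comparison, with 14056 IDs, of which 67 were changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The changed IDs were drawn only from IDs with a mean read number above the minimum of the filter. Changes at low reads were therefore not simulated. In the first simulation the spread was equal for every ID, and 70 of 245 calls (28.6%) were unchanged IDs, far above the 5% that the threshold aims for. It called 68.7% of IDs changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, and 5 IDs when nothing was changed. The simulation was altered after this outcome, and the fit was not. With a spread that varied between IDs, 5 of 119 calls (4.20%) were unchanged IDs. The fit then called 5.97% of IDs changed 1.5-fold, 67.2% of those changed 2-fold and 98.5% of those changed 4-fold, and 0 when nothing was changed. This varying spread was drawn with the 4.48 prior degrees of freedom fitted to the real libraries, and in the form that the fit assumes. The 4.97 that the fit returned on it is therefore close by construction and does not test the simulation. A share of false calls near 5% was likewise built in, so the 4.20% does not give the share among the real calls. With the equal spread the fit returned 22.1. The share of false calls differed between these simulations.

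Alternatives covered scaling, filters, pseudocounts, the variance prior, the time term, the gene model length, limma-voom on the recovered reads and leaving out each library.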

Results

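The series asked how 12 h and 24 h of UNC9994 at 15 µM change the transcriptome of MMQ cells. UNC9994 is a ligand of the dopamine D2 receptor, the receptor through which dopamine restrains prolactin secretion by the pituitary. The 4 libraries held 17433867 to 21728374 recovered reads, and between 13639 and 14092 IDs reached 10 reads in a library. Abundance was ranked once, by mean reads over the 4 libraries. The top ID of this ranking took 2.77% of the reads in DMSO at 12 h (95% Wilson interval 2.77 to 2.78) and 2.83% in DMSO at 24 h (2.83 to 2.84). The share was 2.24% in UNC9994 at 12 h (2.23 to 2.24) and 2.48% in UNC9994 at 24 h (2.47 to 2.48), intervals that cover counting error only. The 10 top IDs of the same ranking together took 9.11% to 9.85% of the reads in every library.

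Libraries of the same treatment were closer to each other than libraries of different treatments. Across the 14056 tested IDs, the SD of the log2 difference was 0.32 between the DMSO libraries and 0.33 between the UNC9994 libraries. It was 0.48 between treatments at 12 h, 0.43 between treatments at 24 h, and 0.45 and 0.47 for the pairs that differed in both treatment and time. The first principal component held 60.5% of the variance and separated the treatments, with scores of -24.9 and -22.1 for the DMSO libraries and 27.1 and 19.8 for the UNC9994 libraries. The second held 21.9% and separated 12 h from 24 h in both treatments. The third held 17.6%, not much less. It set DMSO at 12 h and UNC9994 at 24 h (11.4 and 14.0) against DMSO at 24 h and UNC9994 at 12 h (-14.1 and -11.3).

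The first comparison asked which transcripts changed with UNC9994 at both times. Of the 14056 IDs tested, 1204 changed, of which 479 rose and 725 fell (limma, time and treatment terms, adjusted p under 0.05). Among them, 114 rose and 286 fell by 2-fold or more on the log2(FPKM + 0.5) scale, and 316 changed by less than 1.5-fold. The median absolute log2 change of the called IDs was 0.83, against a median standard error of 0.12. An unadjusted p under 0.05 was reached by 3988 IDs. The number of calls depended on the fit. limma called 0 IDs with no filter on low reads and 0 with no variance trend, where 3795 and 3660 IDs had an unadjusted p under 0.05, and 1991 with a stricter filter. With the time term dropped, it called 851 IDs in all 4 libraries. Leaving out 1 library as well left that treatment with a lone library, assumed to vary like the other treatment. The fit then called 86 IDs without the DMSO 12 h library, 116 without the DMSO 24 h library, 443 without the UNC9994 12 h library and 782 without the UNC9994 24 h library. In a simulation with equal spread for every ID, 28.6% of the calls of this fit were unchanged IDs, and with a spread varying between IDs 4.20% were. The varying spread had the form that the fit assumes, which favours a low share. The share of false calls among the real calls is not known.

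ENSRNOG00000009734 rose from 5.23 to 50.4 FPKM at 12 h and from 2.25 to 26.8 FPKM at 24 h. Its fold was 9.63 at 12 h (95% counting interval 8.48 to 11) and 11.9 at 24 h (9.69 to 14.7), with a common log2 fold change of 3.23 ± 0.11 (SE, 4 libraries) and a limma adjusted p of 0.0045. ENSRNOG00000047225 rose from 13.5 to 58.0 FPKM at 12 h and from 1.92 to 43.1 FPKM at 24 h, a log2 fold change of 3.12 ± 0.46 (limma adjusted p = 0.024). Its vehicle values differed between the times, and its fold was 4.29 at 12 h (3.58 to 5.17) and 22.5 at 24 h (14.1 to 38.2). With the time term dropped, its log2 fold change was 4.38 without the DMSO 12 h library and 1.85 without the DMSO 24 h library.

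ENSRNOG00000052226 fell from 19.4 to 0.524 FPKM at 12 h and from 8.99 to 0.590 FPKM at 24 h. It was 37.0-fold lower at 12 h (25.9 to 54.7) and 15.2-fold lower at 24 h (10.7 to 22.5), with a log2 fold change of -3.70 ± 0.29 (limma adjusted p = 0.0069). ENSRNOG00000020616 fell from 30.8 to 1.54 FPKM at 12 h and from 16.2 to 1.89 FPKM at 24 h. It was 20.04-fold lower at 12 h (15.5 to 26.4) and 8.59-fold lower at 24 h (6.69 to 11.2), with a log2 fold change of -3.37 ± 0.28 (limma adjusted p = 0.0076). All 4 IDs kept their direction in every alternative fit. Their selection for the largest changes, in the same direction at both times, made this near certain. With no variance trend their adjusted p-values were 0.052 for ENSRNOG00000009734, ENSRNOG00000020616 and ENSRNOG00000052226 and 0.076 for ENSRNOG00000047225. With no filter on low reads they were 0.11 for ENSRNOG00000009734, ENSRNOG00000020616 and ENSRNOG00000052226 and 0.15 for ENSRNOG00000047225. ENSRNOG00000047225 also missed the threshold with robust moderation (adjusted p = 0.31), without the time term (0.068), without the UNC9994 12 h library (0.16) and without the UNC9994 24 h library (0.099), the last 2 fitted with no time term. ENSRNOG00000009734 missed it without the DMSO 24 h library, also fitted with no time term, where its log2 fold change was 2.70.

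**Figure D1:**
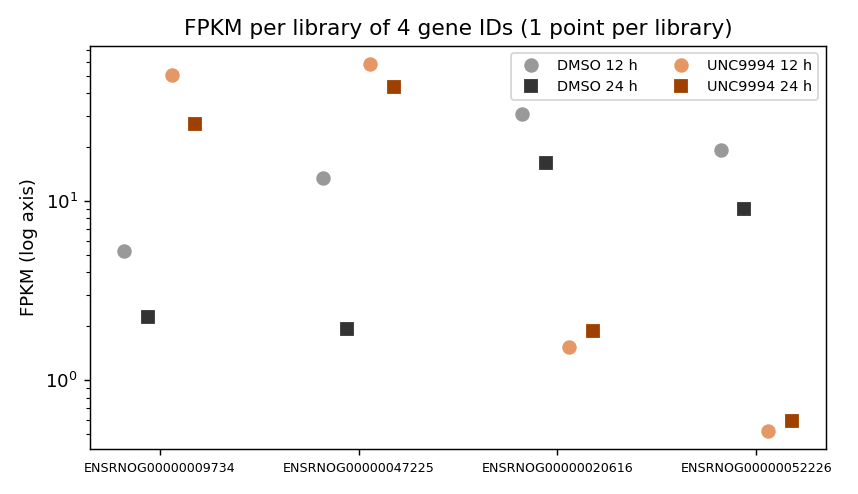
FPKM on a log axis of the 4 printed IDs, with 1 point per library, grey for DMSO and brown for UNC9994, circles for 12 h and squares for 24 h. Both UNC9994 points lie above both DMSO points for ENSRNOG00000009734 and ENSRNOG00000047225, and below them for ENSRNOG00000020616 and ENSRNOG00000052226.

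IDs without an Ensembl number and Ensembl IDs differed in direction. Of 787 IDs without an Ensembl number tested, 67 changed (8.51%), of which 51 rose and 16 fell. Of 13269 Ensembl IDs, 1137 changed (8.57%), of which 428 rose and 709 fell. The odds that a called ID had risen were 5.27 times as high for IDs without an Ensembl number (95% interval 2.91 to 10.04, Fisher's exact test, two-sided, p = 6.6e-10, adjusted over 5 tests of ID groups 3.3e-09). The odds of being called did not differ detectably (odds ratio 0.993, interval 0.756 to 1.29, Fisher's exact test, two-sided, p = 1). These tests treat IDs as independent, which they are not.

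Rises and falls were also unevenly spread over gene model length. Tested IDs were put into 4 length classes of nearly equal size. IDs without an Ensembl number, which mostly rose when called, were not separated from Ensembl IDs in these classes. In the class of the shortest gene models, up to 1329 bases, 177 IDs rose and 210 fell. In the class of the longest, above 3505 bases, 83 rose and 169 fell (odds ratio 1.71, interval 1.22 to 2.42, Fisher's exact test, two-sided, p = 0.0013, adjusted 0.0033). Among IDs with a mean of at least 100 FPKM, 27 rose and 44 fell of 784. They did not differ detectably from the rest in how often they were called (odds ratio 1.07, interval 0.818 to 1.37) or in direction (odds ratio 0.925, interval 0.542 to 1.55). Among IDs with a mean under 1 FPKM, 32 rose and 22 fell of 1613, which was not tested.

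The change with time in culture was smaller. In the same fit, 0 IDs passed the threshold for a difference between 24 h and 12 h common to both treatments (smallest limma adjusted p 0.071), and 1041 had an unadjusted p under 0.05. limma-voom on the recovered reads also called 0. The stricter filter called 22, robust moderation 5 and a pseudocount of 0.1 called 2.

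The second set of comparisons set single libraries side by side, with no replicate and no test. At 12 h, 137 IDs were at least 2-fold higher and 354 at least 2-fold lower with UNC9994, out of 10766. At 24 h, 103 were higher and 218 lower out of 10760. Between 12 h and 24 h in DMSO, 32 were higher and 50 lower at 24 h out of 10660, and in UNC9994 54 were higher and 48 lower out of 10715. Counting error alone gave 0 such IDs in each of these comparisons. The drug pairs thus held 491 and 321 such IDs and the time pairs 82 and 102.

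**Figure D2:**
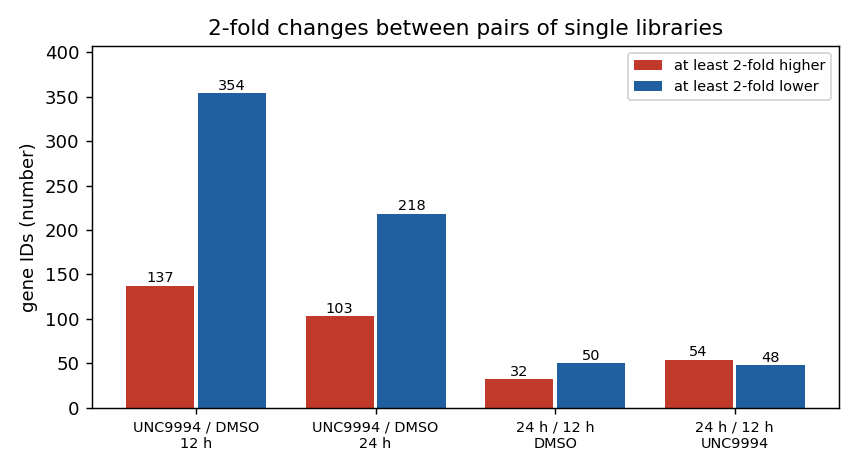
Number of gene IDs at least 2-fold higher (red) or lower (blue) between pairs of single libraries, with 1 library per bar pair member and no error bars. The bars reach 137 and 354 at 12 h and 103 and 218 at 24 h for UNC9994 over DMSO, and 54 or fewer for 24 h over 12 h.

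The responses at 12 h and 24 h, which share no library, had a Pearson correlation of 0.58 and a Spearman correlation of 0.68 across 10922 IDs, which are not independent replicates. Of the 504 IDs that were 2-fold different at 12 h, 450 (89.3%, 95% Wilson interval 86.3 to 91.7) had the same sign at 24 h. The number 2-fold higher at both times was 44, where independent lists would share 1.45, and the number 2-fold lower at both was 136, against 7.17. The changes with time in DMSO and in UNC9994, which also share no library, had a Pearson correlation of 0.10 and a Spearman correlation of 0.16. Of the 91 IDs that were 2-fold different with time in DMSO, 41 (45.1%) had the same sign in UNC9994.

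**Figure D3:**
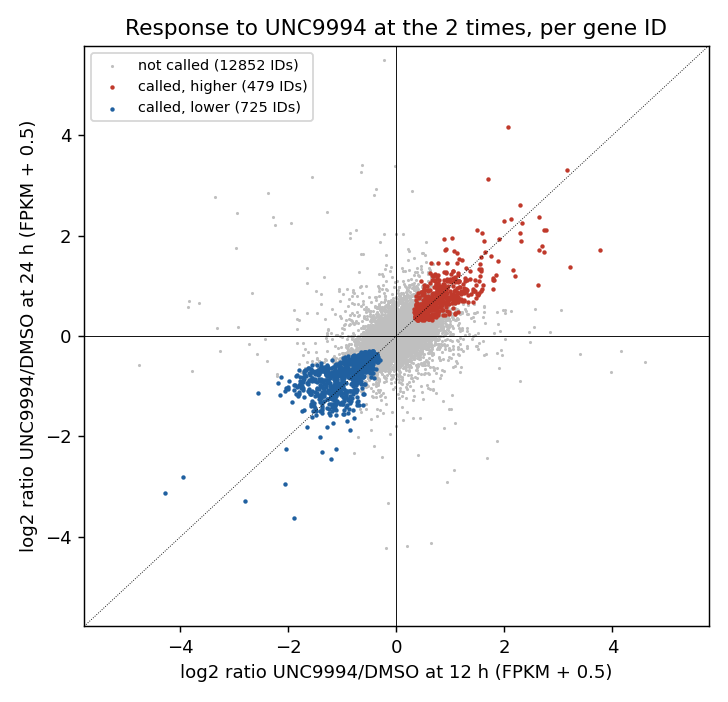
Log2 ratio of UNC9994 to DMSO at 12 h (horizontal) and at 24 h (vertical) on the log2(FPKM + 0.5) scale for the 14056 tested IDs, with 479 called higher in red, 725 called lower in blue and the rest in grey. The called IDs lie in the quadrants where both times have the same sign, which the test for a common change selects, and the dotted line marks equal ratios.

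The response itself differed between the times by 2-fold or more for 187 IDs, 95 with the higher ratio at 24 h and 92 with the higher ratio at 12 h. Counting error around an additive response gave a mean of 4.1 and at most 7 such IDs. This difference could not be tested, because it uses every degree of freedom of the 4 libraries. Among the 725 IDs that fell, the ratio was further from 0 at 12 h for 512 and at 24 h for 213, and their median absolute log2 ratio was 0.93 at 12 h and 0.74 at 24 h. Among the 479 that rose, it was further from 0 at 12 h for 260 and at 24 h for 219, with medians of 0.75 and 0.73. These counts by direction were made with the deposited scaling only. With total-read scaling, the 2-fold changes at 12 h were 162 higher and 321 lower, instead of 137 and 354. At 24 h they were 101 higher and 223 lower, instead of 103 and 218.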

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

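The test of scaling and the test of well-covered IDs below were chosen or reworded after related results had been seen, and the other tests were fixed before theirs. The test of well-covered IDs first required the reads in every library, which leaves out IDs that fell, and was replaced by a mean over libraries. The earlier form had also shown fewer rises than falls. A small group of IDs moved in opposite directions at the 2 times: 5 were at least 2-fold higher with UNC9994 at 12 h and at least 2-fold lower at 24 h, and 9 were at least 2-fold lower at 12 h and at least 2-fold higher at 24 h. This difference was not tested, since each value rests on 1 library.

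More of the called IDs fell (725) than rose (479). Rescaling to total reads left 39.98% of calls higher and median-of-ratios scaling 39.0%, but the median log2 change of all IDs was then only 0.023 and 0.0018, too small a shift to test scaling, which stays open. Removing the trend on gene model length left 39.5%. The median log2 change of the length classes lay only between -0.017 and 0.017, so the removal could hardly move this share. It therefore cannot decide on length. Falls outnumbered rises in each length class, with 45.7% of calls higher in the shortest and 32.9% in the longest. The imbalance was thus not limited to a single length class. IDs with a mean of at least 100 reads numbered 10607. Among them, 24.8% of the 2-fold changes at 12 h and 29.6% at 24 h were rises. The pair counts at a CPM of at least 5 held 10766 and 10760 IDs, with 27.9% and 32.1% rises. The cut on reads thus kept a set of nearly the same size and could hardly give another share, so it cannot decide on precision. Falls also outnumbered rises among these 2-fold changes, which were counted without the fit. The imbalance among calls was narrower with limma-voom on the recovered reads (46.6% higher) and, with the time term dropped, wider without the DMSO 12 h (32.6%), DMSO 24 h (35.3%), UNC9994 12 h (29.35%) or UNC9994 24 h library (25.8%), and a repression by the drug stays open as an untested hypothesis.

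More IDs differed 2-fold at 12 h (491) than at 24 h (321), a ratio of 1.53. Thinning all libraries to the 17433867 reads of the shallowest gave a mean ratio of 1.53 (1.49 to 1.58 over 20 draws), which argues against read depth. The UNC9994 24 h library gave 1.17 times as many changes against the DMSO 12 h library as against the DMSO 24 h library, too few for the DMSO 12 h library to be the cause alone. The UNC9994 12 h library gave 1.49 times as many changes as the UNC9994 24 h library when both were set against DMSO at 24 h (477 and 321 IDs). Against DMSO at 12 h the numbers were 491 and 376. Pairs across times also hold the change with time, which these numbers do not separate. The excess thus went with the UNC9994 12 h library against either vehicle library, by an amount that is not settled. With 1 library per group, a stronger early response and a peculiarity of that culture or library both stay open.

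The called IDs without an Ensembl number mostly rose (51 of 67). Ensembl IDs matched on length and mean FPKM reached that share in 0 of 1000 draws (median 44.4%, highest 72.1%), which argues against length and abundance. Such IDs could have been found because the UNC9994 libraries held more of their reads: among those with at least 50 reads in both DMSO libraries, 75.8% of calls were rises (25 of 33, 95% Wilson interval 59.0 to 87.2), against 33.1% for Ensembl IDs. The interval lay above the share that this explanation had predicted, but reached just below the 60% set as the bound against it. The values thus go against this explanation without excluding it. A drug effect on such loci cannot be told apart from it by these bounds. Their positions are not known here, and transcription running past annotated gene ends was not tested.

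The 4 libraries allow too few splits for a share under 0.05. Without the time term, the real split called 851 IDs and was the only 1 of the 3 splits into 2 and 2 with as many, while the highest other called 0.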

How the results depend on the processing

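Settings named here as pseudocounts, variance trend, length trend, thinning and total-read scaling of the fitted effect were chosen after seeing the data, as were the reported pseudocount and filter and the alternatives for the difference between times. Of 56 alternative values of the main results, 38 stayed within 1.5 times the reported count or within its interval. Median-of-ratios scaling, with factors between 0.999 and 1.002, could change most of these counts only little. Some alternatives for the time effect set 0 calls against 0. The tally is therefore not a measure of robustness. The treatment effect gave 0 calls with no filter, 0 with no variance trend, 1991 with a CPM of at least 5 in 2 libraries (1014 shared with the reported 1204), and, with the time term dropped, 851 in all 4 libraries, 86 without the DMSO 12 h library, 116 without DMSO 24 h, 443 without UNC9994 12 h and 782 without UNC9994 24 h. The causes of these shifts were not tested. Its other fits gave 803 to 1596 calls, between 39.0% and 46.6% of them higher. The time effect gave 22 calls with a CPM of at least 5, 5 with robust moderation and 2 with a pseudocount of 0.1. Requiring a CPM of at least 1 gave 168 IDs for 24 h against 12 h in DMSO, 176 in UNC9994 and 380 for the difference between times. Requiring at least 20 gave 35, 45 and 81, gave 189 for the drug at 24 h, and raised the same-sign share to 94.0%. Of 60 alternative values of the printed IDs, 0 reversed and 13 missed the threshold. A reversal was unlikely from the start, because the printed IDs were chosen for the largest changes. With a simulated spread varying between IDs, the fit called 5.97% of 1.5-fold changes, which were placed only among better-covered IDs. The time term already sets drug against vehicle within each time. Pairing by replicate number was not possible, because each group has 1 library. DESeq2 and edgeR fits were not run, and limma-voom was the only fit made on the recovered reads. Gene set tests were not run, because the IDs have no names here.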

Other observations

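Among IDs with a mean of 10 to 100 FPKM, 253 rose and 453 fell of 6538, and among those with a mean of 1 to 10 FPKM, 167 rose and 206 fell of 5121. In the shorter of the middle classes of gene model length 124 IDs rose and 170 fell, and in the longer 95 rose and 176 fell. The direction in these classes was not tested. No ID had 0 recovered reads in both libraries of one treatment and at least 10 in both of the other (0 in each direction). IDs with a few reads in one treatment, or absent at a single time, are not covered by this rule.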
